A study of Rattus norvegicus with 2 samples.

How the data were processed

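Total RNA from rat liver, 1 sample per diet, had been hybridised to arrays whose probe sets carry Affymetrix names. The deposited table holds 1 signal intensity per probe set and array on a linear scale, and the authors' steps from scanned image to these intensities (background, summarisation and any scaling to a target) are not given in the sources used here. The scale was read from the values, which are never negative, have 1 decimal and reach 9119.2 on the low-fat and 9255.6 on the high-fat array. The 2%-trimmed means of the deposited intensities were 56.9 and 52.6. Each array was taken as 1 sample, and its diet from the sample title. The deposited table gives no detection calls, so the floor used here stands in for them. The number of arrays, 1 per diet, limits the precision of every value.

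The table had 15923 probe sets, of which 57 controls were left out of all gene values. Of the other 15866, 12783 had 1 gene symbol in the platform annotation, 312 had several and 2771 are unnamed here. Symbols with an Entrez identifier in the reference gene table of assembly GRCr8 (12748 probe sets) were looked up there, and none changed. Older symbols in the gene lists were matched through that table's synonyms. No genome was used, and the intensities carry no coordinates, so no positions are given. A gene missing from a list was either unnamed here or not measured.

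Signals were put on the log2 scale with no pseudocount, after 4 probe sets with a 0 on an array were removed. The floor of an array was its median. A probe set was measured where its mean log2 signal over both arrays reached the mean of both floors. The log2 ratio of high-fat over low-fat was centred on its median over measured probe sets, which was -0.117 before centring, against -0.061 for 18 hybridization control probe sets. Where a gene had several probe sets, the one with the highest mean signal was used. A gene was counted as different at 2-fold. A fold with 1 array below its floor is given as a bound against that floor.

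For each of 36 gene lists, the median log2 ratio of measured members was given with a 95% order-statistic (binomial) interval for lists of 6 or more. Members are not replicates, so the interval describes only the spread between them. For lists with 5 or more measured members, 30 in all, the median was ranked among 10000 random lists of the same size, drawn within 10 bins of mean signal. A list was called apart when its median lay among the lowest or highest 2.5% of the random medians. Of the 30, 8 were apart on the lower side and 4 on the higher side. Percentiles describe these arrays and are no test of diet, and some lists share members.

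The gene lists, the floor, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 12 highest and 12 lowest genes above both floors, up to 3 bounds per direction, up to 4 measured members of each list with the largest ratio, and a fixed set of metabolic genes where measured, among them Fasn, Scd, Srebf1, Cpt1a, Cyp4a1, Pdk4, Pck1, Cyp7a1 and Cd36. Other genes of that set are not reported here. A few other list members are given for context and were chosen after their values were seen (Elovl5, Fgb, Hp, Jun, Klf6, Pgk1, Pdia3, Hyou1, Canx, Per1 and Nr1d1, and the second probe sets of Clock and Cry2). The alternatives were no centring, quantile normalization, loess, 2 other floors, no floor, values set to the floor, a pseudocount of 50, the median over a gene's probe sets, removal of probe sets that can cross-hybridise by name, and unmatched random lists. Centring on the hybridization controls was added after the data were seen.

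The procedure was tested on simulated data with the signals and spread of these arrays. Among 5981 simulated measured genes it put 100 of 100 genes with a 4-fold change and 42 of 99 with a 2-fold change past 2-fold in the right direction, and 31 of 5782 unchanged genes past 2-fold. It called 3.5% of random lists of 15 genes apart, and 87.5% of such lists raised by 0.3. The simulated noise was independent between genes, so these rates do not cover lists whose members vary together. Nor does the simulation measure variation between animals. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.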

Results

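Liver RNA was profiled on 2 rat oligonucleotide arrays, 1 for a low-fat diet and 1 for a high-fat diet. Rats of the SD strain were described as 4 weeks old and fed for 9 weeks. The fat content of the diets, the sex of the rats and the number of animals behind each RNA are not given in the sources used here. Both diets were built on AIN93G, a standard purified rodent diet. The comparison asked which liver transcripts differed between the diets. With 1 array per diet there was no replicate check and no test of diet, so every difference below describes these 2 arrays only and carries no p-value. Higher and lower mean the sign of the high-fat over low-fat log2 ratio after it was centred on the median of measured probe sets.

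The arrays were close in overall signal. The median signal over 15866 probe sets was 15.7 on the low-fat array and 14 on the high-fat array, and these medians served as the detection floors. Of 10411 genes with a single symbol, 6012 were measured. Log2 signals of the 7864 measured probe sets correlated with r = 0.978 across probe sets, which are not independent replicates. The robust SD of the log2 ratio narrowed from 0.487 among the dimmest of 10 equal bins of measured probe sets to 0.171 among the brightest. In the 696 genes with a second measured probe set, the difference between their log2 ratios had an SD of 0.417, and 56.9% of these pairs had the same sign. Of 10 genes past 2-fold with a second probe set, 8 had the same sign on it and 3 were past 2-fold on it too. The 3′/5′ signal ratio of the beta-actin control was 2.69 on the low-fat array and 2.85 on the high-fat array, and that of the Gapdh control was 1.58 and 1.67.

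Among measured genes, 51 were at least 2-fold higher and 52 at least 2-fold lower on the high-fat array. At least 3-fold differences numbered 5 and 4. One array was below its floor for 24 of the 51 and 23 of the 52. On simulated arrays with the same spread, the same steps put 31 of 5782 unchanged genes past 2-fold. That noise was normal, with the robust SD of these arrays' own ratios, and the spread between animals is unknown. The 31 therefore do not estimate false calls among the 51 and 52. The counts of 51 and 52 depended on the floor, and at each array's 75th percentile 15 genes were higher and 10 lower.

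The genes with the lowest ratios included several of carbohydrate and fat metabolism. Rgs16, a regulator of G-protein signalling, was 3.87-fold lower on the high-fat array, from a signal of 72.1 to 17.2. Slc2a5, the fructose transporter GLUT5, was 3.55-fold lower, from 78.9 to 20.5. Acaca, which makes malonyl-CoA for fatty acid synthesis, was 2.85-fold lower, and Acly, which supplies its acetyl-CoA, was 2.65-fold lower, from 404.9 to 140.9. Me1, the cytosolic malic enzyme that yields NADPH, was 2.40-fold lower, and its second probe set had a log2 ratio of -0.66. Gcnt2, a glycosyltransferase, was 2.89-fold lower and Eif4ebp3, a repressor of translation initiation, 2.43-fold lower. Fabp5, a fatty acid binding protein, was 2.35-fold lower. Stxbp2, Rbck1, Tepsin and Pura were 2.64-, 2.32-, 2.22- and 2.21-fold lower, all with high-fat signals below 20. Kcnj15, a potassium channel gene, Tmem88 and Lztfl1 were below the high-fat floor and at least 2.88-, 2.58- and 2.25-fold lower.

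The genes with the highest ratios were led by the tubulin gene Tubb2a, 5.13-fold higher at 145.6 against 30.8. A second tubulin gene, Tuba4a, was 2.43-fold higher. Rpl37a, encoding a ribosomal protein, was 3.18-fold higher, from 797.0 to 2339.7, on its single measured probe set. Lox, which cross-links collagen, was 2.94-fold higher, and its second probe set had a log2 ratio of 1.90. Kynu, a tryptophan-degrading enzyme gene, was 2.43-fold higher, from 329.3 to 737.6, and Prodh, the first enzyme of proline breakdown, was 2.36-fold higher. The sulfotransferase gene Sult1c2a was 2.52-fold higher, Ubd, a ubiquitin-like modifier, 2.39-fold, the small heat shock gene Hspb1 2.39-fold, and Ltc4s, the leukotriene C4 synthase, 2.32-fold. Nras and Atosb were 2.65- and 2.56-fold higher, with low-fat signals near the floor. Fam111a, Chmp2b and the chemokine gene Cxcl13 were below the low-fat floor and at least 2.66-, 2.47- and 2.31-fold higher. Sult1c2a, the tubulins and Rpl37a belong to families of similar sequence, and their probe sets cannot be assigned with certainty to 1 member.

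**Figure D1:**
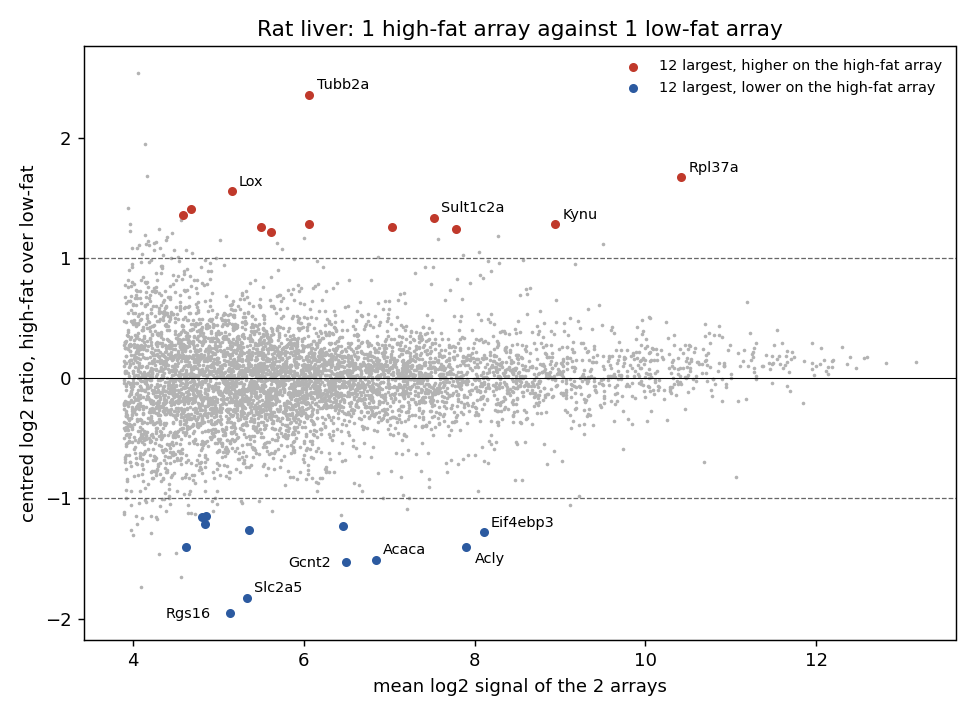
Each point is 1 of the 6012 measured genes, with the mean log2 signal of the 2 arrays on the x axis and the centred log2 ratio of the high-fat over the low-fat array on the y axis. Dashed lines mark 2-fold, and the 12 highest and 12 lowest genes above both floors are coloured, with Tubb2a at 2.36 and Rgs16 at -1.95.

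Fatty acid synthesis genes were mostly lower on the high-fat array. Of 13 measured members, 10 were lower, 3 of them past 2-fold, and 3 were higher. The median log2 ratio was -0.39, with an interval across members of -1.26 to 0.20. Besides Acaca, Acly and Me1, Fasn, the fatty acid synthase, had log2 ratios of -0.94 and -1.43 on its 2 probe sets. Scd, the stearoyl-CoA desaturase, went from 2190.7 to 1244.1 (-0.70). Srebf1, a transcription factor that activates this pathway, was on the other side at 0.66, with the same value on its second probe set, and the elongase gene Elovl5 was at 0.51. None of 10000 random lists matched on signal had a median as low. Glycolysis genes were lower in 8 of 10, with a median of -0.19 and an interval of -0.71 to 0.006. The list was at percentile 0.14, and at percentile 4.48, not apart, against unmatched random lists. The lowest glycolysis members were Pfkfb1 (-0.72), Gpi (-0.71) and Pklr, the liver pyruvate kinase gene (-0.55, and -0.93 on a second probe set). Pgk1 was at -0.04 and at 0.50 on its second probe set.

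Cholesterol synthesis and uptake genes were split. Of 15 measured members 9 were lower and 6 higher, none past 2-fold, and the median was -0.23, with an interval of -0.34 to 0.33 and percentile 0.59. Fdps and Mvk, enzymes of isoprenoid synthesis, were at -0.64 and -0.50, while Insig1, a regulator of sterol sensing, and Dhcr7, a late enzyme, were at 0.64 and 0.52. The second probe set of Mvk was at -0.17. The percentile of this list was 13.9 when the floor was lowered to the 25th percentile of each array.

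Median differences in the fatty acid breakdown lists were small. In the mitochondrial oxidation and ketogenesis list 13 of 19 members were higher, with a median of 0.13 at percentile 93.4, which was not apart from random lists. That median was 0.01 without centring, where 11 of 19 members were higher. Bdh1, Decr1 and Acadm were at 0.46, 0.40 and 0.38. Cpt1a, which controls entry of fatty acids into mitochondria, was at -0.35, and at -0.33 on its second probe set. In the list of peroxisomal oxidation and Ppara targets 15 of 20 members were lower, with a median of -0.10, an interval of -0.28 to -0.002 and percentile 1.9. Pex11a, Angptl4 and Crat were at -0.78, -0.67 and -0.55, and Cyp4a8, below the low-fat floor, was at least 1.61-fold higher. The second probe set of Pex11a was at -0.12. Cyp4a1 and Pdk4, both standard Ppara targets, were at 0.03 and -0.05, and the sign of Cyp4a1 flipped with the scaling. The percentile passed 2.5 under 4 alternatives, among them loess correction (2.85) and random lists without matching on signal (9.8).

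Gluconeogenesis genes had a median of -0.21 over 8 members, with an interval of -0.98 to 0.27 and percentile 0.08. Of these 5 were lower and 3 higher, and 7 lower and 1 higher without centring or with quantile normalization. The low values belonged to the aminotransferase genes Got1 (-0.98) and Gpt (-0.85) and to the glucose-6-phosphate transporter gene Slc37a4 (-0.39). Pck1, the rate-controlling enzyme, was at 0.05, and the sign of that value flipped with the scaling. The percentile was 4.78 with unmatched random lists.

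Acute phase and complement genes were higher in 20 of 21 members on the high-fat array (15 higher and 2 lower with quantile normalization), with a median of 0.25, an interval of 0.14 to 0.35 and a percentile of 100. A2m and Lcn2, both acute phase genes with low signal here, were past 2-fold at 1.13 and 1.01. Lcn2 was below 2-fold under some scalings, down to 0.89. The ratios of more abundant transcripts were smaller, with Hamp, the iron hormone hepcidin, at 0.40, C1s at 0.40, Fgb at 0.26 and Hp at 0.12. Hepatocyte markers, which are similarly abundant, had a median of 0.14, and after loess correction of the ratio on signal the medians were 0.16 for the acute phase list and 0.02 for hepatocyte markers. The acute phase list then had 18 of 21 members higher and its interval was 0.02 to 0.26.

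All 11 measured circadian clock genes were lower on the high-fat array under every scaling run. Their median was -0.67, with an interval of -0.78 to -0.17, and no random list reached it. The lowest were Usp2, a clock-controlled deubiquitinase (-0.97, and -0.75 on a second probe set), the repressor gene Bhlhe40 (-0.78), and Dbp and Hlf, transcription factors driven by the clock (-0.71 each). Per1 was at -0.69 and Nr1d1 at -0.37. Second probe sets of Clock and Cry2 went the other way, at 0.84 and 0.11. Immediate early genes, which respond within minutes to stimuli, were lower in 9 of 10, with a median of -0.47, an interval of -0.65 to -0.05 and percentile 0.01. Egr1, Zfp36, Dusp1 and Ier2 were at -0.83, -0.65, -0.59 and -0.52, and the second probe set of Dusp1 was at -0.22. Jun was at -0.21, and its second probe set went the other way, at 0.70. Klf6, the member that was higher, was at 0.15 and at -0.24 on its second probe set. The hour of tissue collection and the feeding state are not given in the sources used here.

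**Figure D2:**
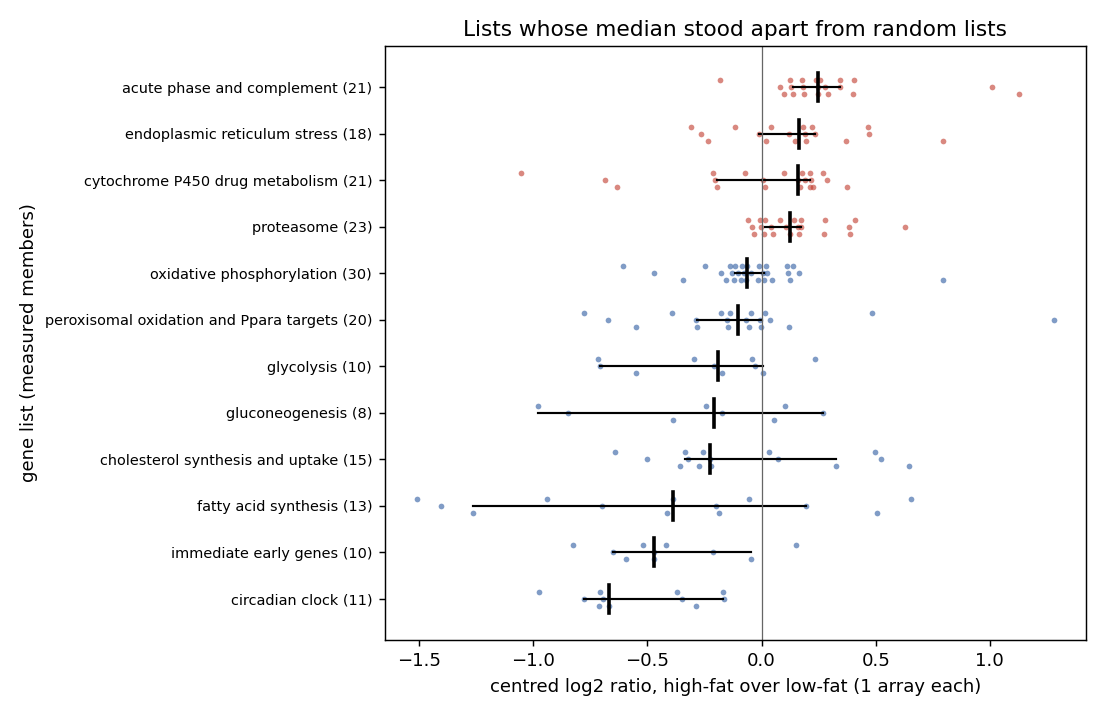
Each row is 1 of the 12 gene lists whose median stood apart from 10000 random lists matched on signal, with points for measured members, a thick bar for the median and a line for its 95% order-statistic interval across members. The x axis is the centred log2 ratio of the high-fat over the low-fat array; medians run from 0.25 for acute phase genes to -0.67 for circadian clock genes.

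Bile acid genes were not apart, with a median of 0.14 at percentile 96.3 over 17 members, but were apart with quantile normalization, at percentile 99.2, and with loess. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the proportion of cholic acid, was at 0.95, from 435.2 to 773.8. The phospholipid transporter gene Abcb4 was at 0.57. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.13. Lipoprotein genes were higher in 15 of 15 members, but in 9 of 15 without centring, and their median of 0.15 was not apart (percentile 95.4). Triglyceride and lipid droplet genes went both ways, 6 higher and 6 lower, with a median of 0.06, which was -0.05 without centring, and a mean of -0.07. Their percentile was 71.5, and 2.24, apart on the lower side, with the floor at the 75th percentile. Lpin1, a phosphatidate phosphatase, was at -0.94, the lipase gene Mgll at -0.77, the fatty acid transporter gene Cd36 at 0.77 with a signal near the floor, and G0s2, an inhibitor of lipolysis, at 0.50.

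Cytochrome P450 genes had a median of 0.16 and a mean of -0.02, and the list's percentile of 99.2 became 83.3 after loess correction. Por, the reductase that supplies electrons to these enzymes, was the lowest member, at -1.05 and at -1.18 on a second probe set. Cyp2c12 was at -0.69 and the xenobiotic receptor gene Nr1i2 at -0.64. In the conjugation and Nrf2 list, with a median of 0.08 that was -0.04 without centring, Ugt2b1 was at -1.09 and Aldh1a1 at 0.65. Endoplasmic reticulum stress genes were higher in 13 of 18, with a median of 0.16 at percentile 98.7. The count was 11 of 18 and the median 0.05 without centring. The highest members were Creld2 (0.79) and the chaperones Hspa5 and Calr (0.47 each). Second probe sets went the other way for Pdia3 (0.18 and -0.12), Hyou1 (0.12 and -0.80) and Canx (-0.01 and 0.14). That percentile was 84.9 when probe sets of a gene were combined by their median. Proteasome genes were higher in 18 of 23, with a median of 0.12 at percentile 97.525, and in 12 of 23 without centring. That percentile was 96.1 to 97.35, and so not apart, under 5 alternatives, among them quantile normalization (96.98). Oxidative phosphorylation genes were lower in 19 of 30, and in 25 of 30 without centring, with a median of -0.06 at percentile 0.15, and at percentile 16.6 against unmatched random lists.

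Markers of other cell types were examined for a difference in tissue composition. Macrophage and Kupffer cell markers had 6 members higher and 6 lower, with a median of -0.02, and 2 higher and 10 lower without centring. Endothelial markers had 3 higher and 3 lower, with a median of 0.01 that was -0.10 without centring. Stellate cell and fibrosis markers were lower in 6 of 7, with a median of -0.28 at percentile 3.9, which was not apart. The percentile was 2.13, and so apart, with a pseudocount of 50, and it was also apart from unmatched random lists. Among them Vim was at -0.59, and Col1a2, below the high-fat floor, was at least 1.97-fold lower, while its second probe set was at 0.07. The lymphocyte and neutrophil lists had no measured member. Hbb, the beta-globin gene of red cells, was at 0.08, the adipocyte gene Cfd at 0.02 and the pancreatic gene Cela1 at -0.15. The signs of Hbb and Cfd flipped with the scaling.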

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

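The tests of the antiphase clock genes, of hepatocyte markers and of the median over probe sets were chosen after their values had been seen, and the other tests below were fixed before theirs were.

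The 1059 measured probe sets without a single gene symbol entered the centring, the correlation and the bins of signal, but not the gene counts or gene lists. Of these, 4 were at least 2-fold higher on the high-fat array than on the low-fat control array. Another 10 were at least 2-fold lower.

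The clock list was lower in all 11 members. A trend of the ratio with signal is argued against, since after loess the median was -0.64, with an interval of -0.77 to -0.14. A different time of day of the livers stays open: it predicts opposite movement of genes that peak opposite to Dbp and Per1, and only 2 were measured, Clock and Nfil3, with a median of -0.42. Both are also members of the clock list, and the second probe set of Clock was at 0.84. Lower glucocorticoid signalling also stays open, although the percentile of 40.3 and median of 0.004 over 8 other glucocorticoid-induced genes met the bounds set beforehand against it, because these genes went both ways, with an interval of -1.03 to 0.925, and such a median decides nothing. With 1 array per diet, diet cannot be told apart from either.

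The fatty acid synthesis list was lower, and a trend of the ratio with signal is argued against, since its median was -0.395 after loess against -0.389. The list also stayed at percentile 0, but those random lists were already matched on signal. The choice of probe set stays open. As 7 of the 10 lower members had a single measured probe set, a median over probe sets could change little. The percentile of 0 with that median therefore decides nothing. All 3 lower members with a second probe set were lower on it too, but the number is too small to decide. A candidate explanation is lower carbohydrate-responsive transcription in the high-fat liver. It was tested on 9 further targets of the carbohydrate-responsive factor. Of these 7 were lower, among them Txnip (-0.84), Pgd (-0.54), Tkfc (-0.475) and Gpd1 (-0.47), and 2 were higher, Mid1ip1 (0.30) and Rpia (0.07). The median of -0.40 lay at percentile 0.01, but its interval of -0.54 to 0.07 included 0. The carbohydrate content of the diets and the feeding state are not given in the sources used here. These values therefore cannot single out this explanation, and differences between the samples other than diet stay open.

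The acute phase list was higher in 20 of 21 members, and in 15 with quantile normalization. A trend of the ratio with signal is argued against as the whole cause, since after loess 18 of 21 members were still higher. The median went from 0.25 to 0.16, so part of it may be such a trend, and its interval was 0.02 to 0.26. The list also stayed at percentile 99.9, but those random lists were already matched on signal, so that percentile decides little. A larger share of hepatocyte RNA stays open: hepatocyte markers had a median of 0.144, with an interval of 0.04 to 0.174. The acute phase median of 0.246 lay above that interval, the bound set against this explanation, but its own interval of 0.14 to 0.345 overlapped it. Diet itself stays open and untested.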

How the results depend on the processing

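Centring on the hybridization controls was chosen after the data were seen. No paired analysis was possible because each diet had 1 array, and for the same reason no replicate could be left out and no other split of the samples exists. The counts of genes at least 2-fold higher and lower, 51 and 52, depended most on the treatment of low signals: they were 244 and 318 with a floor at the 25th percentile, 15 and 10 at the 75th, 836 and 996 with no floor, and 4 and 4 with a pseudocount of 50, which shrinks ratios of dim genes by construction. With values set to the floor 35 genes were higher and 34 lower, and without centring 33 were higher and 78 lower. Without centring the median of all measured genes shifts by -0.117, and 29.7% of calls were higher against 49.5%; with quantile normalization, a floor at the 75th percentile and centring on the controls that share was 57.8%, 60.0% and 41.0%. Agreement in sign of a second probe set, 80.0% of 10 genes past 2-fold, was 46.6% with no floor, 67.6% with the 25th percentile floor, and 100% with the 75th percentile floor and with the pseudocount; it has no value with the median of probe sets. No list median that stood apart changed sign. Of 15 list medians that left their interval, those of lists that stood apart were, without centring, -0.34 for cholesterol synthesis, 0.13 for acute phase, -0.79 for circadian clock, -0.18 for oxidative phosphorylation and 0.008 for proteasome; 0.115 for acute phase with quantile normalization; and -0.12 for oxidative phosphorylation centred on the controls. The percentiles of fatty acid synthesis, acute phase, circadian clock and immediate early genes stayed past their limit under all alternatives that gave a value. Every ratio shifts by the same amount without centring and on centring to the controls, so no percentile could change under these settings. The 75th percentile floor left fewer than 5 members, and so no value, for immediate early, stellate, endothelial and cell cycle genes. Calls were lost for cytochrome P450 (80.5 with quantile normalization, 83.3 with loess, 95.4 without _x_at and _s_at probe sets), proteasome (96.98 with quantile normalization, 97.0 and 96.5 with floors at the 25th and 75th percentile, 97.35 with no floor, 96.1 unmatched), Ppara targets (2.85 with loess, 4.85 with the 75th percentile floor, 3.49 with the pseudocount, 9.8 unmatched), endoplasmic reticulum stress (92.6 with the 75th percentile floor, 84.9 with the median of probe sets, 97.3 without _x_at and _s_at), cholesterol synthesis (13.9 with the 25th percentile floor), and, unmatched, gluconeogenesis (4.78), glycolysis (4.48) and oxidative phosphorylation (16.6). Over all alternatives 10 percentiles gained a call, for bile acid (up to 99.2), pericentral (up to 99.2), ribosomal (down to 0.49), stellate (down to 2.13) and triglyceride genes (2.24). Causes of these losses and gains were not tested. Of 1646 alternative values of the 154 named genes, 52 moved by more than the spread at their signal and none past 2-fold changed sign. Under at least 1 scaling the sign of Cfd, Cyp4a1, Hbb, Pck1 and Pf4 flipped, and Hspa1a and Serpina1 reached 0.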

Other observations

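Several genes outside the naming rule were picked after their values were seen and are given for context only. Insig2, an endoplasmic reticulum protein that restrains processing of sterol regulatory factors, was 2.26-fold higher on the high-fat array, from 213.9 to 446.3. Crot, which prepares fatty acids for export from peroxisomes, was 2.07-fold higher, and its second probe set had a log2 ratio of 1.26. Akr1c1, a ketosteroid reductase gene, was 2.25-fold higher. Mt2A, a metal-binding metallothionein gene, had a log2 ratio of -0.83, from 2967.6 to 1544.1.

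Of 22 members of the urea cycle and amino acid list 12 were higher and 10 lower, but 7 and 15 without centring and 8 and 14 with loess or quantile normalization, with a median of 0.02 that was -0.10 without centring, while Kynu and Prodh were at 1.28 and 1.24. Rpl37a, at 1.67, stood far from the 25 measured members of the ribosomal list, which ran from -0.38 for Rps15 to 0.18 for Rps29. The ribosomal list was not apart, at percentile 3.65, but was apart on the lower side with quantile normalization, with loess and with the 75th percentile floor, where its percentile was 0.49. In the interferon and antigen presentation list, with a median of 0.05 that was -0.07 without centring, Oas1a was at -1.02 and Ifit3, below the high-fat floor, at least 1.98-fold lower, while RT1-Ba and Psmb9 were at 0.68 and 0.61. In the growth hormone list, with a median of 0.12, Obp3 was at 0.61 on one probe set and 0.62 on another, and Cyp2c12 at -0.69. Heat shock genes had a median of 0.12, iron and heme genes 0.10, pericentral genes 0.17, periportal genes -0.02, and the 5 measured cell cycle genes 0.21, and none of these lists was apart in the main setting; the pericentral list was apart with no floor, at percentile 99.2, and with the 25th percentile floor. Without centring the heat shock median was -0.001 and the iron and heme median -0.02. Among single markers, Epcam of bile duct cells was at -0.17 and Alas2 of red cell precursors at 0.19. Hsd17b13, a lipid droplet enzyme gene in the periportal list, was at -0.84, from 496.6 to 255.1.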
